A study of Mus musculus with 2 samples.

How the data were processed

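CTCF ChIP-seq was measured in newborn mouse hindbrain, in 1 group of 2 libraries made from a pooled tissue sample. All files are lists of peaks on mm10 in the narrowPeak layout. Each library has a list of 300000 peaks, made from its own alignments and a control alignment, per the deposited descriptions of the files. A pooled list of 251251 peaks came from the alignments of both libraries together, and the conservative and optimal IDR sets were derived by the authors from the pooled and the single-library lists. The aligner, the peak caller, the IDR version and its threshold, and the antibody lot are not given in the sources used here. The deposited signal value of each peak is a score on the caller's own scale, with no stated unit. It was used to rank, filter and describe peaks within a list. Levels were compared between lists only for the 2 IDR sets and the pooled list. All 62686 optimal and 59979 conservative peaks are in the pooled list at the same position, with a signal equal to within 0.001%. A test of chromosome X set a signal limit 2 times higher on autosomes, which assumes that signal is proportional to copy number. The deposited q value is on a −log10 scale and is shared at its maximum by 79.6% of the optimal peaks, so peaks were not ranked by it. The deposited IDR score ran from 537 to 1000 in both IDR sets and was 0 throughout the other lists. Of the remaining columns, the p column holds no value, and the summit offset in bp gave each peak's summit. The files give no read counts, so the depth of the libraries is unknown here, and precision is given only as counting error over peaks, genes or pairs. The tissue label of both libraries and their replicate numbers were taken from the labels. Control libraries were not used here.

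The reference was the GRCm38 assembly (patch release of mm10) with GENCODE vM21 annotation. Peaks on chromosomes 1 to 19, X and Y were kept for analyses that need the genome, which left out 9 of the 62686 optimal peaks. Peaks were annotated by their summit, in the order promoter (within 1 kb of a start site of any annotated gene), exon, intron and intergenic. Random expectations came from 1000 placements of the same number of positions on the same chromosomes, outside assembly gaps. The replicate lists were compared by overlap of at least 1 bp among their 62686 strongest peaks, with 5 random placements of a peak list.

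The consensus CCASYAGRKGGCRS (14 bp) was searched on both strands within 50 bp of each summit, allowing 2 mismatches, and the best match gave the strand. Windows 1 kb to each side and the reversed, not complemented, consensus served as background, compared by exact McNemar tests over peaks. Signal deciles were taken over the optimal set. For orientation, each motif-bearing peak was paired with the next one along the chromosome, leaving out 26 peaks whose best matches tied between strands, and strands were reassigned at random 1000 times. Densities have exact Poisson intervals, and the ratio of X to autosomes an exact binomial interval.

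For gene lists, a gene counted as occupied with a summit within 1 kb of any of its annotated start sites. The lists were Hox genes, clustered protocadherins, imprinted genes, cohesin and CTCF factors, cytosolic ribosomal proteins, housekeeping genes, olfactory receptors and markers of hindbrain patterning, cerebellar granule lineage, forebrain, neurons, glia, liver, and vessels, meninges, blood and microglia. Every list was tested by Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over 14 lists and a threshold of 0.05. From each list the text names up to 4 members with the strongest promoter peak and up to 3 without one, the first in alphabetical order. All 19 loci and the 10 strongest optimal peaks are named too. The lists, the loci, the tests and this rule were fixed before the data were examined. For olfactory receptors, only members with a peak are named. Some members that this rule would name are not reported here. Loci ran from the first to the last member with 10 kb on each side, and were compared with 10000 random windows that hold at least 1 gene. Matched gene lists, added after the data were seen, were drawn 10000 times from the same decile of promoter CpG ratio (1001 bp around the start) and the same class of start site number.

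Alternatives fixed beforehand were the conservative set, the 31343 strongest optimal peaks, the 62686 strongest peaks of each library alone (setting the other replicate aside) and merging of summits under 150 bp apart. They also included promoters of 500 bp and 2.5 kb, protein-coding genes or 5' ends only, 1 or 3 mismatches, motif pairs with no motifless peak between them, windows of 25 or 100 bp, flanks at 5 kb, locus margins of 50 kb, a reciprocal overlap of 50% and summits within 50 bp. Where motif shares were corrected for their flanks, the flank share was subtracted and the difference divided by the share of flanks without a match. Further tests used GC content over 251 bp around the summit, soft-masked repeats, a scan of the consensus over the whole genome, and the identity of 40 bp around neighbouring motifs with a limit of 60%. The number of pairs that would all have to point the same way was computed from the observed and the random share. Intervals for differences between shares there came from 200 bootstrap draws.

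Steps were tested on simulated data with known answers. Over 20000 simulated windows the motif scan found 100% of implanted motifs, called 1.88% of windows without an implant and gave the right strand for 99.6%. Implants had at most 2 mismatches, so finding them all checks the code and not the sensitivity at real sites. The overlap step had 0 disagreements with a brute-force count over 2400 intervals. For 60480 uniformly placed peaks the promoter ratio was 0.995 (permutation p = 0.761). For 20000 motifs with implanted convergent pairs, the orientation step found 32.0% convergent, as simulated (permutation p = 0.00498). The simulated share was counted from the same strands, so this match too checks only the code. Over 21911 genes, 97.7% of simulated lists of 25 genes raised from an occupancy of 30% to a mean of 71.4% were called, and 1.5% of unchanged lists. Smaller differences were not simulated. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.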

Results

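Binding sites of CTCF, the zinc finger protein that marks the boundaries of chromatin loops and insulates neighbouring genes, were mapped in the hindbrain of newborn mice. The hindbrain holds the developing cerebellum, pons and medulla. Tissue was taken on postnatal day 0 from mice of the strain B6NCrl, and the hindbrains of several dissections were pooled and pulverised. CTCF-bound DNA was recovered with an antibody against CTCF and sequenced (ChIP-seq). The labels give 1 group of 2 libraries, numbered as biological replicates 1 and 2, and name the same pooled tissue sample for both, so the spread between them may be technical. The sex of the pups was not collected. Each library came with a list of 300000 candidate peaks, and the pooled reads gave a list of 251251. The authors filtered these by the irreproducible discovery rate (IDR), a measure of how well peak ranks repeat between lists. This gave a conservative set of 59979 peaks and an optimal set of 62686. The read depth of the libraries is unknown here because the files hold peaks and not read counts. The signal value of a peak is the caller's own, on a scale that is not stated, and served to rank and describe peaks within a list. It was compared between lists only for the 2 IDR sets and the pooled list, from which all peaks of both sets carry their value. Coordinates are on mm10, and intervals on shares and densities are 95% intervals that cover counting error only.

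The first question was how far the 2 libraries listed the same binding sites. Of the 62686 strongest peaks of replicate 1, 54144 (86.4%, Wilson interval 86.1 to 86.6) overlapped a peak among the 62686 strongest of replicate 2 by at least 1 bp. The share in the other direction was 86.2%. Peaks placed at random on the same chromosomes overlapped in 1.45% ± 0.0601 (SD over 5 placements). The overlap depended on how far down the lists the comparison went. It was 76.0% for the 1000 strongest peaks, 94.5% for the 20000 strongest and 46.8% for all 300000, where random placement gave 7.45%. Among the optimal peaks, 62371 of 62686 (99.5%) overlapped a peak in both lists, and 52228 (83.3%) overlapped a peak within the 62686 strongest of both. Spearman's rho between the ranks of these peaks in the 2 libraries was 0.944. How far the ranks in the 2 libraries decided the optimal set was not tested. Any selection for ranks that repeat between them would raise both the share of 99.5% and this correlation. It is a correlation across peaks, which are not independent replicates, and no p is given for it.

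**Figure D1:**
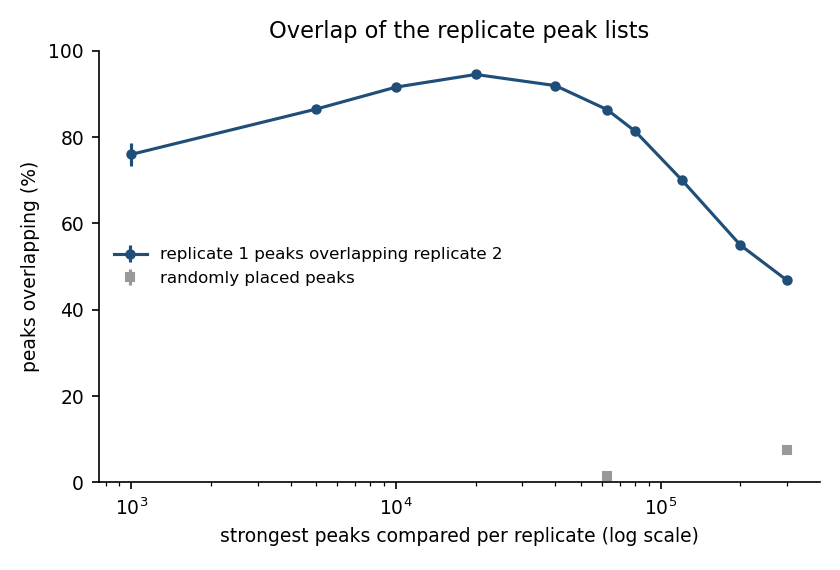
Percent of replicate 1 peaks that overlapped a replicate 2 peak, against the number of strongest peaks taken from each list (log scale); bars on the points are Wilson intervals and grey squares are randomly placed peaks with their SD. The overlap was highest at 20000 peaks (94.5%) and lowest with all 300000 (46.8%), while random placement gave 1.45% at 62686 and 7.45% at 300000.

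The conservative and the optimal set shared most of their peaks, and neither contained the other. Of the optimal peaks, 54586 of 62686 (87.1%, Wilson interval 86.8 to 87.3) were overlapped by a conservative peak. The 8100 optimal peaks outside the conservative set had a median signal of 25.04, against 93.1 for the shared ones. In the other direction, 5434 conservative peaks had no overlapping optimal peak, and their median signal was 24.96. Identical summits were found for 54243 peaks. The optimal set was used for all that follows.

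CTCF sites lay at gene starts more often than random positions did. Of the 62677 optimal peaks on the assembled chromosomes, 13168 (21.0%, Wilson interval 20.7 to 21.3) had their summit within 1 kb of an annotated transcription start site, against 6.38% of random positions, a ratio of 3.29. Exons outside promoters held 5.18% of summits against 3.41% at random (ratio 1.52), and intergenic sequence held 33.8% against 49.95% (ratio 0.676). For each of these classes the permutation p was 0.001, the smallest that 1000 random placements can give (two-sided). Introns held 40.045% of summits against 40.258% at random (ratio 0.995, permutation p = 0.258). The intron ratio was the only one to change direction with the processing. It was 1.03 with promoters of 500 bp and 1.05 with protein-coding genes only, and 0.935 with promoters of 2.5 kb, each with a permutation p of 0.001.

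The CTCF core sequence was then searched at the summits. A match to the consensus CCASYAGRKGGCRS with at most 2 mismatches lay within 50 bp of the summit in 41011 of 62677 peaks (65.4%, Wilson interval 65.1 to 65.8). The share was 34.7% with at most 1 mismatch and 86.3% with at most 3. Windows of the same length centred 1 kb to the left and right held a match in 2.85% and 2.98%, and the reversed consensus matched 1.76% of the summit windows. Peaks with a match at the summit and none on the left numbered 39856, and the opposite case 629. On the right these numbers were 39780 and 635. The exact McNemar p for each of these differences was too small for the software to represent. The median distance from the match to the summit was 6.5 bp. Matches lay on the plus strand in 49.8% of cases.

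Stronger peaks held the motif more often. The share rose from 35.6% (Wilson interval 34.4 to 36.8) in the weakest decile of signal to 91.4% (90.6 to 92.0) in the strongest, while the share in flanking windows stayed between 2.75% and 3.26%. Spearman's rho over all 62677 peaks was 0.361, again across peaks. The motif was least frequent at promoters. There 6115 of 13168 peaks (46.4%, Wilson interval 45.6 to 47.3) had a match, against 65.9% in exons, 69.1% in introns and 72.9% (72.2 to 73.4) in intergenic sequence. Promoter peaks with the motif had a median signal of 113.5, and those without it 44.2.

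**Figure D2:**
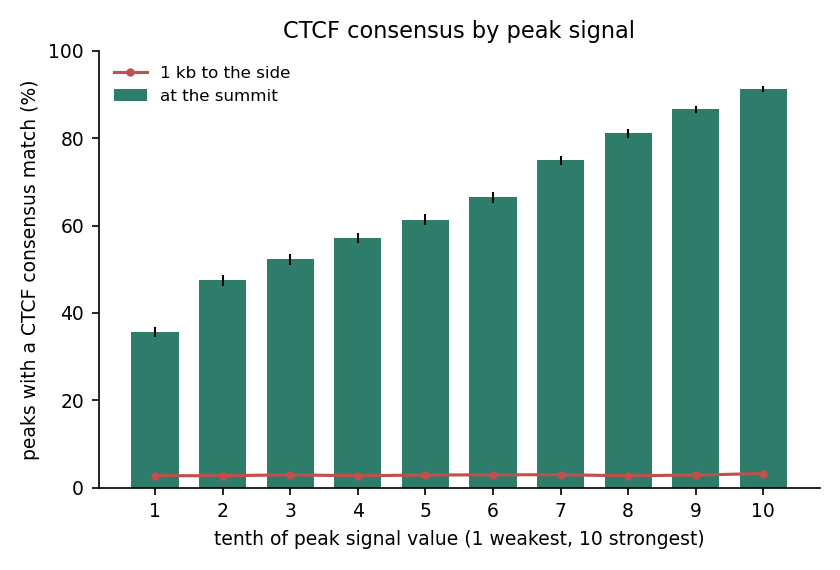
Percent of optimal peaks with a CTCF consensus match within 50 bp of the summit (bars, with Wilson intervals) by decile of peak signal value, and the percent in windows 1 kb to the side (line). The share at the summit was 35.6% in decile 1 and 91.4% in decile 10, and the flanking share was at most 3.26%.

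Of the 10 peaks with the largest signal value, 9 carried the motif. The strongest lay in an intron of Fam129b on chromosome 2 (32912435 to 32912796), with a signal of 684.6, ranks of 4 and 2 in replicates 1 and 2, and the sequence CCAGCAGGCGGCAG at 32912596 to 32912609 on the plus strand. The next lay in intergenic sequence on chromosome 7 (137478253 to 137478651), 9858 bp from Glrx3, a glutaredoxin gene, with a signal of 679.4. The third, on chromosome 5 (120102772 to 120103133), lay 13514 bp from Rbm19 with a signal of 673.0 and a perfect match, CCACCAGGGGGCGC, at 120102930 to 120102943 on the minus strand. Promoter peaks followed at Pick1 on chromosome 15 (79243196 to 79243551, signal 646.5), Rrp1 on chromosome 10 (78412937 to 78413296, 646.4) and Iqsec1 on chromosome 6 (90737428 to 90737781, 641.5). An intron of Pink1, a mitochondrial kinase gene, held the next on chromosome 4 (138319528 to 138319886), with a signal of 636.0 and the perfect match CCACTAGGTGGCGC. The last ones were intergenic. They lay 4369 bp from Stmn1 on chromosome 4 (134478020 to 134478401, signal 631.1), 6566 bp from Hif1an on chromosome 19 (44582654 to 44583030, 630.6) and 2277 bp from Kcnk18 on chromosome 19 (59239480 to 59239841, 628.6). The peak near Hif1an was the one without a match, its best sequence having 3 mismatches.

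The strand of the motif sets the direction in which CTCF sits on DNA, and CTCF sites at the feet of chromatin loops mostly point towards each other. Among 40965 pairs of neighbouring motif-bearing peaks, the orientation changed with distance. Pairs pointing towards each other (convergent) made up 19.5% (Wilson interval 18.6 to 20.5) of 7191 pairs under 5 kb apart and 33.3% (31.5 to 35.2) of 2469 pairs over 200 kb apart, against 25% with strands reassigned at random. In the bins from 5 to 20, 20 to 50, 50 to 100 and 100 to 200 kb the convergent share was 20.4%, 23.4%, 27.7% and 30.1%. Pairs pointing apart (divergent) went from 25.5% (24.5 to 26.5) under 5 kb to 14.8% (13.4 to 16.2) over 200 kb. Pairs pointing the same way made up 55.0% (53.8 to 56.1) under 5 kb, against 49.98% at random.

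In each of the 6 bins the convergent share differed from random with a permutation p of 0.001, the smallest that 1000 strand reassignments can give (Benjamini-Hochberg adjusted p = 0.0015 over 18 tests). From 50 to 100 kb this call was lost when pairs with a motifless peak between them were left out, where 24.9% of 3100 pairs were convergent (adjusted permutation p = 0.885), and the other bins kept it. For divergent pairs the adjusted permutation p was 0.325 under 5 kb and 0.886 from 20 to 50 kb, and 0.0015 in the other bins. For pairs pointing the same way it was 0.0503 from 50 to 100 kb and 0.0753 over 200 kb, and passed in the other bins. With the pairs around a motifless peak left out, pairs pointing the same way passed in each bin, at 52.5% to 56.2%. Over all distances the shares were 23.7% convergent, 23.7% divergent and 52.6% in the same direction, each with a permutation p of 0.001. These overall departures from random were absent with at most 1 mismatch, where 21721 pairs gave 25.02%, 25% and 49.98% (permutation p = 0.924, 0.974 and 0.942). Split by distance at this limit, a comparison added after the data were seen, 18.2% of pairs under 5 kb and 35.1% of pairs over 200 kb were convergent, and the convergent share passed in each bin (adjusted permutation p = 0.00163). Pairs pointing the same way passed under 5 kb at 54.4% (adjusted permutation p = 0.00163), but not at 51.6% from 5 to 20 kb (0.0527), 49.9% from 20 to 50 kb (0.935) or 49.6% from 100 to 200 kb (0.674). Their share lay below random from 50 to 100 kb (48.0%, adjusted permutation p = 0.0154) and over 200 kb (47.6%, 0.00830). Divergent pairs gained the call under 5 kb and from 20 to 50 kb (27.4% in each) and lost it from 50 to 100 kb (24.1%, adjusted permutation p = 0.188).

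**Figure D3:**
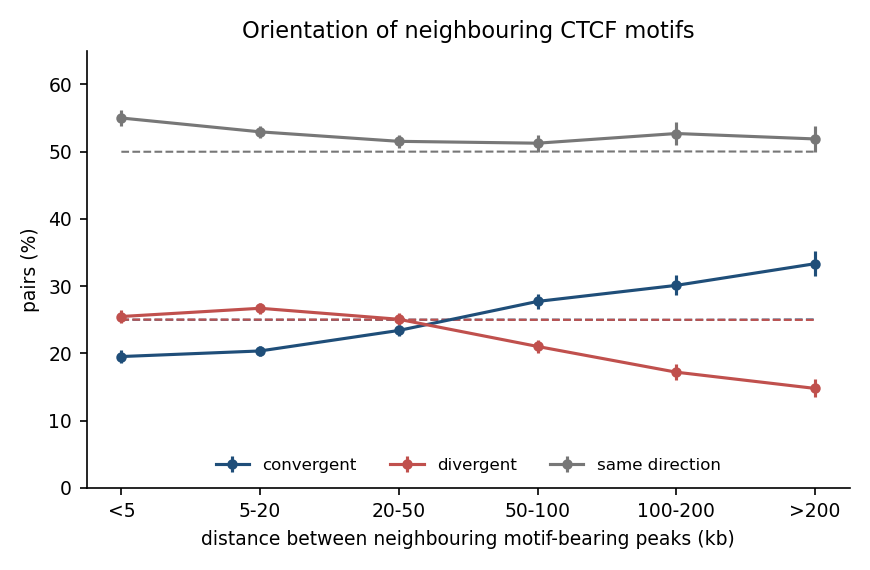
Percent of neighbouring motif-bearing peak pairs that were convergent, divergent or in the same direction, by distance between the peaks in kb; bars are Wilson intervals and dashed lines the mean of 1000 random strand reassignments. Convergent pairs went from 19.5% under 5 kb to 33.3% over 200 kb, and divergent pairs from 25.5% to 14.8%.

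Chromosome X held fewer sites per Mb than the autosomes. Its 1414 peaks amounted to 8.27 per Mb (exact Poisson interval 7.84 to 8.71), against 24.9 per Mb on the autosomes, a ratio of 0.332 (exact interval 0.315 to 0.350). Chromosome 11 was the densest with 37.1 peaks per Mb (36.1 to 38.2), and chromosome 3 the sparsest autosome with 18.7 (18.0 to 19.4). No optimal peak lay on chromosome Y. With assembly gaps left out of the lengths, the ratio of X to autosomes was 0.338. By region, also without gaps, it was 0.457 at promoters (exact interval 0.402 to 0.518) and 0.385 in exons (0.279 to 0.518). Introns had a ratio of 0.422 (0.385 to 0.462) and intergenic sequence 0.340 (0.314 to 0.368). Each region thus lay above the ratio for all regions together. Among the 10000 strongest optimal peaks, 48 lay on X, a ratio over full lengths of 0.0695 (0.0512 to 0.0922). The dose of X in the pooled pups is unknown, since their sex was not collected.

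Promoter occupancy was compared across 14 gene lists fixed before the data were examined. Of 21911 protein-coding genes, 8727 (39.8%) had a peak summit within 1 kb of an annotated start site. Each list was tested against all other protein-coding genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 14 lists. Promoters differ in CpG content and in their number of start sites. Occupancy was 58.1% among 10067 genes with a CpG ratio over 0.6 at the promoter and 24.3% among the other 11844. Each list was therefore also set against 10000 random lists matched on both, a comparison added after the data were seen. The matched p values are permutation values, adjusted in the same way. Both tests and the Wilson intervals count each gene as independent. Members of a gene cluster are neighbours and can share a peak. For protocadherins, Hox genes and olfactory receptors the p values may thus be too small and the intervals too narrow.

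Clustered protocadherins, the cell-surface proteins whose combined expression gives neurons their identity, were occupied more often than other genes. Of 56 members, 42 (75%, Wilson interval 62.3 to 84.5) had a promoter peak (Fisher's exact test, adjusted p = 8.92e-07), against 33.4% in matched lists (adjusted permutation p = 0.0014, from the smallest p the draws can give). Most of these peaks were weak, with a median signal of 42.0. The strongest was at Pcdhac1 on chromosome 18 (37089822 to 37090101, signal 398.4), followed by Pcdhga12 (143.6), Pcdhgc3 (139.5) and Pcdhgb6 (114.7). Pcdha2, Pcdha8 and Pcdhb1 had none. Among the 31343 strongest optimal peaks the share was 12.5%, no longer above the 20.2% of other genes (Fisher's exact test, adjusted p = 0.426).

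Olfactory receptor genes, silent in most tissues, stood at the other end. Of 1092 genes, 10 (0.916%, Wilson interval 0.498 to 1.68) had a promoter peak (Fisher's exact test, adjusted p = 3.19e-226), against 8.44% in matched lists (adjusted permutation p = 0.0014). Olfr557 on chromosome 7 (102695459 to 102695691) had the strongest, with a signal of 292.9, followed by Olfr156 (214.2), Olfr1499 (174.0) and Olfr556 (169.5).

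Hox genes, which set position along the body axis and pattern the hindbrain segments, were occupied less often than other genes. Of 39 genes, 8 (20.5%, Wilson interval 10.8 to 35.5) had a promoter peak (Fisher's exact test, adjusted p = 0.0318), against 44.6% in matched lists (adjusted permutation p = 0.0168). The strongest stood at Hoxa7 on chromosome 6 (52221673 to 52221950), with a signal of 452.9, rank 901 among the optimal peaks and the sequence CCAGGAGATGGCAG on the minus strand. Hoxb5 (302.8), Hoxc5 (247.9) and Hoxa10 (187.5) followed, while Hoxa11 and Hoxa13 had none. By the same exact test, the call was lost with promoters of 500 bp (17.9%, adjusted p = 0.119) and of 2.5 kb (38.5%, adjusted p = 0.238). Other genes then had 32.3% and 49.2%. The Hox call was also lost by this exact test with the 5' end of each gene only (17.9%, adjusted p = 0.167). The same held with the 31343 strongest peaks (15.4%, adjusted p = 0.860, Fisher's exact test). Other genes had 31.9% and 20.2% there.

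Cytosolic ribosomal protein and housekeeping genes were occupied more often than other genes, and the difference from matched genes did not pass the test. Among cytosolic ribosomal protein genes, 52 of 84 (61.9%, Wilson interval 51.2 to 71.6) had a peak (Fisher's exact test, adjusted p = 2.22e-04). Rpl26 on chromosome 11 (68901327 to 68901635, signal 468.3) led, followed by Rps3a1 (444.2), Rpl5 (422.3) and Rplp0 (418.2), and Rpl10l, Rpl12 and Rpl13 had none. Matched lists gave 58.9% (adjusted permutation p = 0.758). Among housekeeping genes, 12 of 16 (75%, Wilson interval 50.5 to 89.8) had a peak (Fisher's exact test, adjusted p = 0.0227), with matched lists at 58.6% (adjusted permutation p = 0.634). Actb on chromosome 5 (142905693 to 142905910, signal 167.5) was the strongest, followed by Gapdh (165.7), Sdha (82.7) and Eef2 (45.1), and Gusb, Hprt and Tbp had none. The housekeeping call was lost without replicate 1 (68.8%, adjusted p = 0.0753), with the 5' end only (43.8%, 0.431) and with the 31343 strongest peaks, where the share was 18.8%, below the other genes (adjusted p = 1), by Fisher's exact test.

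The list of cohesin and CTCF factors holds genes of the cohesin ring and its regulators and of DNA-binding proteins such as CTCF. Its members had a peak in 11 of 17 (64.7%, Wilson interval 41.3 to 82.7), which did not pass the adjustment (Fisher's exact test, adjusted p = 0.0812). The share passed it without replicate 2 (70.6%, adjusted p = 0.0359) and with the 31343 strongest peaks (52.9%, 0.0129), by the same exact test. Matched lists gave 56.0%, and the difference from them did not pass the test (adjusted permutation p = 0.758). Stag1, a cohesin subunit gene, held the strongest on chromosome 9 (100643468 to 100643737, signal 340.2). Esco1 (294.6), Pds5a (247.2) and Maz (244.2) followed, and Ctcfl, Esco2 and Mau2 had none.

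The lists of hindbrain, granule lineage, neuronal, glial and forebrain genes did not pass the test. Of 23 genes of the cerebellar granule lineage, 10 (43.5%, Wilson interval 25.6 to 63.2) had a promoter peak (Fisher's exact test, adjusted p = 0.832). The share was below that of other genes without replicate 1 (39.1% against 40.4%) and with the 31343 strongest peaks (17.4% against 20.2%). With promoters of 500 bp and with the 5' end only it was 21.7%, against 32.3% and 31.9% of other genes. It was also below matched lists (51.8%). None of these differences passed the test. Gli1, a transcription factor of hedgehog signalling, had the strongest on chromosome 10 (127338889 to 127339149, signal 376.5), followed by Gli2 (310.5), Mycn (268.6) and Etv1 (115.3). Atoh1, the transcription factor of granule cell progenitors, Barhl2 and Cbln3 had none. Of 22 hindbrain patterning genes, 6 (27.3%, 13.2 to 48.2) had one (Fisher's exact test, adjusted p = 0.391). They included Egr2, a regulator of hindbrain segments, on chromosome 10 (67536110 to 67536260, signal 135.6), and Wnt1 (120.9) and Irx2 (77.0), but not En1 or En2. The hindbrain patterning share lay below matched lists (49.0%), a difference that did not pass the test (adjusted permutation p = 0.172).

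Neuronal genes had a promoter peak in 11 of 22 cases (50%, 30.7 to 69.3; Fisher's exact test, adjusted p = 0.449). This was 31.8% in the conservative set, with promoters of 500 bp and with the 5' end only. Other genes then had 38.5%, 32.3% and 31.9%. With the 31343 strongest peaks the neuronal share was 18.2%, against 20.2% of other genes. Rbfox3, which encodes the neuronal nuclear antigen NeuN, had the strongest on chromosome 11 (118507932 to 118508237, signal 467.1), at a start site inside the gene. Gap43, a growth cone protein gene (421.6), Elavl4 (258.2) and Gad1 (205.7) followed, and Calb1, Dcx and Elavl3 had none. Glial genes had one in 6 of 18 cases (33.3%, 16.3 to 56.3, Fisher's exact test, adjusted p = 0.687). Their share lay above other genes with promoters of 2.5 kb (66.7% against 49.2%) and with the 31343 strongest peaks (22.2% against 20.2%). None of these changes of direction in neuronal or glial genes came with a passing test. Gfap, the intermediate filament gene of astrocytes, carried a peak of signal 510.3 on chromosome 11 (102900849 to 102901208), rank 238 among the optimal peaks, with a perfect motif match. Pdgfra (310.4), Slc1a2 (166.6) and Olig2 (98.6) followed, and Aqp4, Cspg4 and Fabp7 had none.

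Forebrain genes had a peak in 6 of 25 cases (24.0%, 11.5 to 43.4; Fisher's exact test, adjusted p = 0.235). Bcl11b on chromosome 12 (108004099 to 108004265) had a signal of 170.4, and Eomes (45.7), Vax1 (28.5) and Tbr1 (25.2) were weak, while Dlx1 and Dlx2 had none. This share fell below matched lists (51.4%, adjusted permutation p = 0.0280). Low occupancy against matched lists was not particular to forebrain genes. Hox genes (20.5% against 44.6%) passed the test too, and hindbrain patterning genes (27.3% against 49.0%) lay below without passing it. By Fisher's exact test the forebrain share was also below other genes in the conservative set (12%, adjusted p = 0.0178) and without replicate 2 (12%, adjusted p = 0.0120).

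Genes of other tissues and of cells that accompany brain tissue were seldom occupied. Liver genes had a peak in 2 of 20 cases (10%, Wilson interval 2.79 to 30.1; Fisher's exact test, adjusted p = 0.0185). They were Apob on chromosome 12 (7978571 to 7978865, signal 413.6) and Afp, the fetal serum protein gene (297.0), and not Ahsg, Alb or Ambp. Genes of vessels, meninges, blood and microglia had one in 3 of 21 cases (14.3%, 4.98 to 34.6; Fisher's exact test, adjusted p = 0.0464). They included the collagen genes Col1a1 on chromosome 11 (94939335 to 94939598, signal 356.4) and Col1a2 (66.0), and not Aif1, Alas2 or Cdh5. Neither list differed past the threshold from matched lists, which gave 16.4% and 24.3% (adjusted permutation p = 0.758 and 0.692). Both calls were also lost with promoters of 2.5 kb and with the 31343 strongest peaks. The liver call was lost in the conservative set and the other with the 5' end only.

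Imprinted genes, expressed from a single parental copy, had a promoter peak in 19 of 40 cases (47.5%, Wilson interval 32.9 to 62.5; Fisher's exact test, adjusted p = 0.427). H13 on chromosome 2 (152669265 to 152669541, signal 472.8) led, followed by Blcap (308.3), Commd1 (260.3) and Meg3 (233.7). Cdkn1c, Ddc and Dlk1 had none. Over the 35 protein-coding members the share was 42.9%, against 50.9% in matched lists (adjusted permutation p = 0.692).

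**Figure D4:**
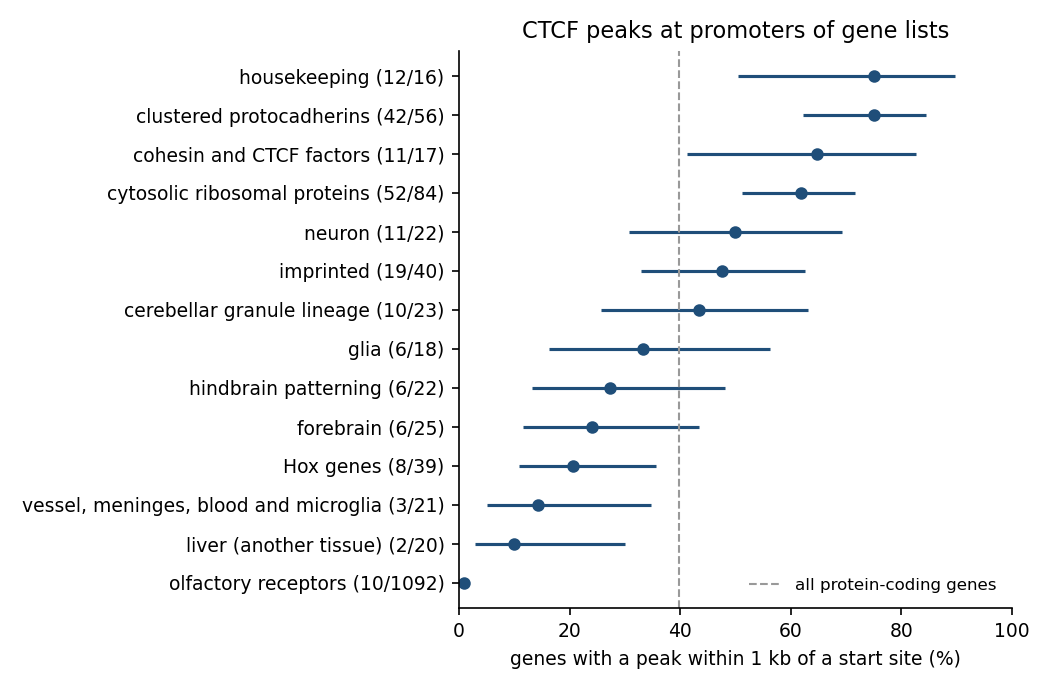
Percent of the genes of each list with a peak summit within 1 kb of an annotated start site, with Wilson intervals and the number of genes in brackets; the dashed line is the share over all protein-coding genes (39.8%). Shares ran from 0.916% of olfactory receptor genes to 75% of clustered protocadherins and housekeeping genes.

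Peak numbers were then counted in 19 loci fixed before the data were examined, each with 10 kb added on both sides, and set against 10000 random windows of the same length that hold a gene. Only Firre stood apart after adjustment. This locus on chromosome X (50545744 to 50645321) encodes a long noncoding RNA that is transcribed from a repeat-rich gene. It held 29 peaks in 99.6 kb (exact Poisson interval 19.4 to 41.6), against a median of 2 in random windows (permutation p = 2.0e-04, the smallest the draws can give, adjusted p = 0.0038). The motif matched at 4 of the 29 peaks with at most 2 mismatches, and 21 others had a best sequence with 3 mismatches. The strongest Firre peak had a signal of 174.3, rank 17180.

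No other locus passed the adjustment. Gnas on chromosome 2 (174274320 to 174356744) held 12 peaks against a random median of 2, and Myc on chromosome 15 (61975391 to 62000374) held 5 against 0 (adjusted permutation p = 0.148 for both). The Hox clusters held 8 peaks in Hoxa, 12 in Hoxb, 4 in Hoxc and 8 in Hoxd, against random medians of 2, 4, 3 and 2. Their adjusted permutation p values were 0.465, 0.446, 0.982 and 0.446. In Hoxa, 4 of the 6 motifs lay on the minus strand, including those at Hoxa7 and Hoxa10. The stronger peak of the others had its motif at 52257121 to 52257134 on the plus strand. In Hoxb 6 of 9 motifs lay on the minus strand. In Hoxd 3 of 4 lay on the plus strand, with signals of up to 320.3. Both motifs in Hoxc lay on the plus strand.

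**Figure D5:**
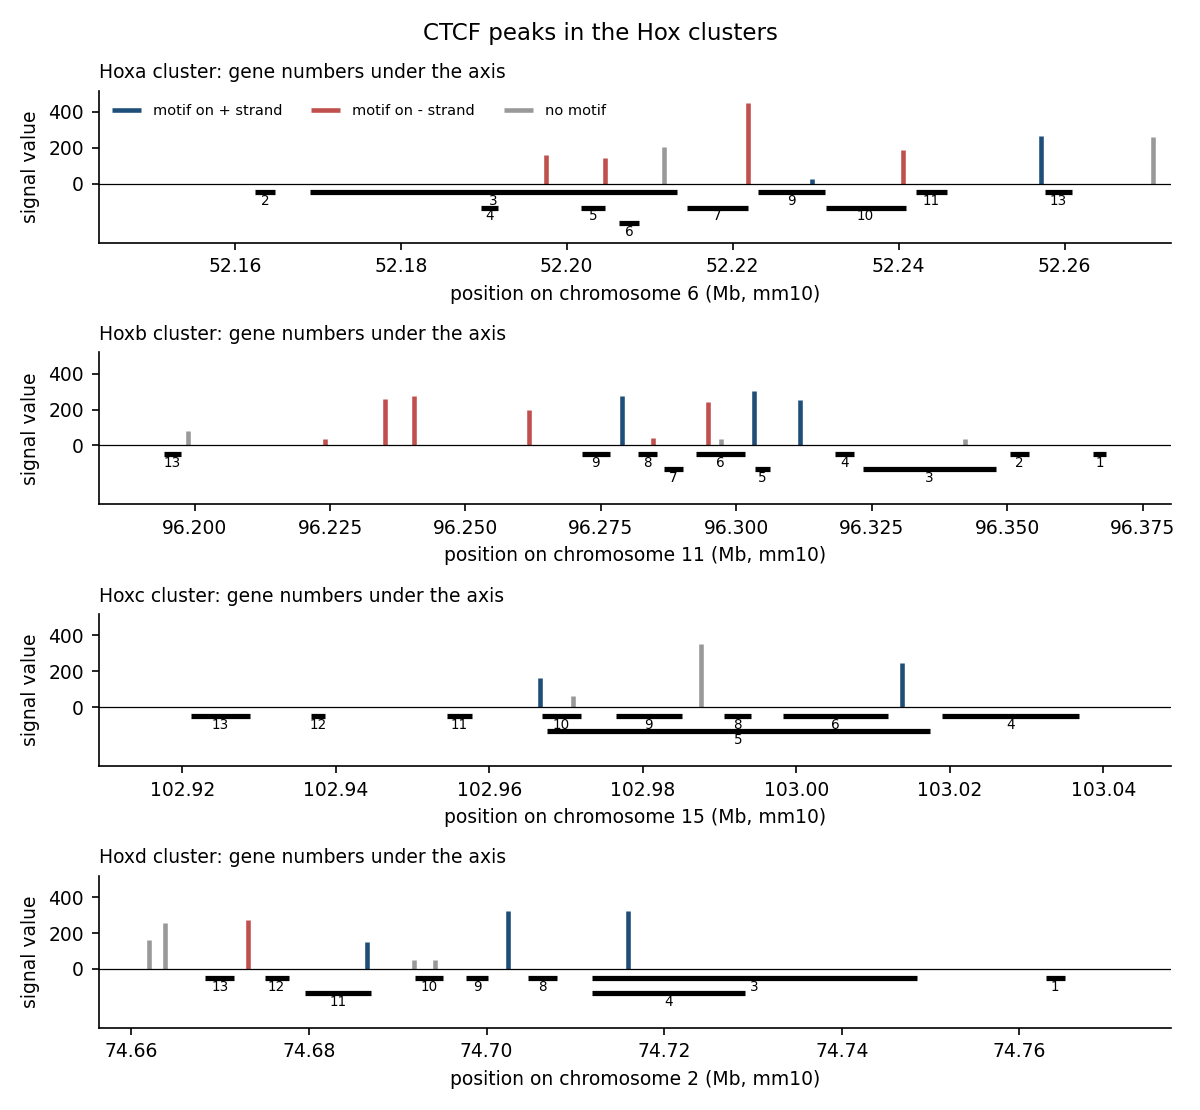
Optimal CTCF peaks in the Hox clusters, drawn at their summit position (Mb, mm10) with height equal to the peak signal value and colour showing the strand of the motif or its absence; black bars under the axis are Hox genes, not all of which are drawn. The strongest peak lies at Hoxa7 (signal 452.9), and the Hoxb cluster holds 12 peaks.

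The protocadherin locus on chromosome 18 (36920184 to 37851873) held 53 peaks in 931.7 kb against a random median of 19 (adjusted permutation p = 0.446). Motifs were found at 13 of them, 10 on the plus strand and 3 on the minus strand, and 21 others had a best sequence with 3 mismatches. Among imprinted loci, H19-Igf2 on chromosome 7 (142565529 to 142676816) held 9 peaks. Its 4 motifs all lay on the minus strand, and the strongest peak (142672220 to 142672468) had a signal of 372.7. None of the H19-Igf2 peaks from 142580215 to 142582175 had a match. At 4 peaks of this locus the best sequence had 3 mismatches. Kcnq1-Cdkn1c, Peg3-Usp29 and Grb10-Ddc held 12 peaks each, with 8, 10 and 8 motifs, and Dlk1-Meg3 held 6 with 4 motifs. The strongest peak of these lay in intergenic sequence on chromosome 7 (143466344 to 143466656) in the Kcnq1-Cdkn1c locus, with a signal of 458.5 and a perfect match.

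At Xist-Tsix, the X-inactivation locus (103421517 to 103494957), 5 of 6 peaks had a motif. The strongest (103484146 to 103484324, signal 212.4) carried a perfect match, CCAGCAGGTGGCAG, on the plus strand. The limb and neural signalling locus Shh-Lmbr1 held 12 peaks in 941.6 kb, against a random median of 19. Mycn held 3 peaks, or 5 without replicate 1, and the Hbb cluster of beta-globin genes 1. No peak lay at En2 or Atoh1, where the random median was also 0. For the loci other than Firre, Gnas and Myc the lowest adjusted permutation p was 0.446.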

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

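Both results in this part were computed after the peak lists had been examined, and none of their tests was planned beforehand. The first concerns peaks of the pooled list that neither IDR set kept, which no comparison above used. Of these 181667 peaks, 27388 (15.1%, Wilson interval 14.9 to 15.2) had the CTCF consensus within 50 bp of the summit, against 2.75% and 2.73% of windows 1 kb to the left and right. The share rose over quintiles of their signal from 6.88% (6.62 to 7.15) to 31.3% (30.8 to 31.8). Their median signal was 9.16. The IDR sets thus leave out a number of motif-bearing positions that carried a weaker signal (median 73.9 in the optimal set), and whether CTCF occupied them was not tested here.

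The second concerns 9 optimal peaks on contigs that are not placed in the assembled chromosomes, which the analyses of genome position left out. They lay on 5 contigs. The highest signal among them was 543.6, on Un_GL456359, and Un_JH584304 held 4 of the 9.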

How the results depend on the processing

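The matched comparison was added after the data were seen, and the other alternatives here were planned. Motif share and the density of chromosome X kept their direction and their side of the threshold under each alternative run (10 and 6 comparisons), though the motif share itself ran from 34.7% with at most 1 mismatch to 86.3% with at most 3. Locus counts kept both in 109 of 114 comparisons, and no locus changed its side of the threshold. The exceptions, past it in neither case, changed direction against random windows. They were the Hoxc (4 peaks) and Hbb (4) clusters, En2 (4) and Atoh1 (3) with margins of 50 kb, and Hbb (1) with the 31343 strongest peaks. Gene lists kept both in 91 of 126 comparisons, lost a call in 16, gained one in 5 and changed direction in 14. These counts include merging of summits under 150 bp apart, which left all 62686 peaks and so tests nothing. Without it they are 9, 5, 90 of 95 and 77 of 112. Replicate overlap was 80.9% with a reciprocal overlap of 50%, 82.3% with summits within 50 bp, 94.0% for the 31343 strongest and 46.8% for all peaks. The rank correlation was 0.966 in the conservative set and 0.952 with summits within 50 bp. The share of optimal peaks met by conservative ones was 86.5% with reciprocal overlap. Intron ratios were 0.964 for the 31343 strongest peaks and 0.935 with promoters of 2.5 kb, and reversed to 1.03 with 500 bp and 1.05 with protein-coding genes only. Spearman's correlation of motif with signal was 0.383 with at most 1 mismatch and 0.354 in the conservative set. With at most 1 mismatch the overall orientation shares crossed the random values, at 25.02% convergent, 25% divergent and 49.98% in the same direction. With no motifless peak between neighbours these shares kept their direction and call, while the convergent share from 50 to 100 kb lost its call (24.9%).

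For gene lists, the conservative set brought forebrain past the threshold (12%), lost liver (15.0%) and reversed neurons (31.8%). The 31343 strongest peaks lost Hox (15.4%), liver (10%) and vessel (9.52%) genes, gained cohesin factors (52.9%), and reversed protocadherins (12.5%), housekeeping genes (18.8%), the granule lineage (17.4%), neurons (18.2%) and glia (22.2%). Leaving out a replicate gave 58.8% to 70.6% for cohesin factors (gained without replicate 2), 12% to 24.0% for forebrain (gained without replicate 2), 68.8% to 75% for housekeeping genes (lost without replicate 1) and 39.1% to 43.5% for the granule lineage (reversed without replicate 1). Hox genes were lost with promoters of 500 bp (17.9%) and 2.5 kb (38.5%), and the latter lost liver (25%) and vessel (23.8%) genes and reversed glia (66.7%). The 5' end alone lost Hox (17.9%), housekeeping (43.8%) and vessel (9.52%) genes. Both it and promoters of 500 bp reversed the granule lineage (21.7%) and neurons (31.8%). Against matched lists, ribosomal (61.9%), housekeeping (75%), liver (10%) and vessel (14.3%) genes no longer passed the threshold. In the same comparison forebrain genes (24.0%) passed it, and the granule lineage (43.5%) and imprinted genes (42.9%) changed direction. Of the lists that changed direction, only protocadherins and housekeeping genes had passed the threshold. Lower shares with fewer peaks, narrower promoters or the 5' end alone follow from the construction. The share of other genes moved too. For the neuronal list it was 38.5% in the conservative set and 20.2% with the 31343 strongest peaks. With promoters of 500 bp, of 2.5 kb and the 5' end only it was 32.3%, 49.2% and 31.9%. The cause of the changed calls and directions was not tested. No paired analysis was possible because there is 1 group. Depth limits could not be set, since the files give no read counts.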

Other observations

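The patterns in this part were noticed first and then tested on the same data, with the limits of each test written before its value was seen; the combined test of chromosome X was added after the separate ones, and the number of similar neighbouring pairs and the signal at perfect motifs on chromosome X were tested after they had been seen. The scan of the whole genome, the repeat counts and the rank differences between the IDR sets were chosen after the report's results were seen.

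Most perfect copies of the consensus in the genome were bound. In this part a match counted as bound if its middle lay within 50 bp of an optimal summit. Matches inside a peak but farther from its summit counted as not bound. Of 6945 matches without mismatch, 5486 (79.0%, Wilson interval 78.0 to 79.9) were bound, against 16669 of 59988 matches with 1 mismatch (27.8%, 27.4 to 28.1). The bound share of perfect copies was 87.7% (83.8 to 90.8) in exons, 87.1% (85.7 to 88.3) in introns, 74.2% (72.6 to 75.6) in intergenic sequence and 69.8% (66.7 to 72.7) at promoters. With matches of at most 1 mismatch the order was another, with 44.2% (43.0 to 45.4) bound at promoters, 38.1% (36.4 to 39.8) in exons, 37.0% (36.4 to 37.6) in introns and 27.4% (26.9 to 27.8) in intergenic sequence. On the autosomes, matches with at most 1 mismatch were bound in 43.9% (43.4 to 44.4) of cases outside repeats and 19.2% (18.7 to 19.7) inside them. Repeats held 23.4% (23.0 to 23.8) of the motifs at peaks and 18.4% (18.1 to 18.7) of all summits.

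The IDR selects peaks by how well their ranks repeat, so rank differences between the sets describe that selection and not the libraries. The median absolute log2 ratio of the 2 ranks, over peaks found in both lists, was 0.66 for the optimal-only peaks (96.3% of 8100 found in both) and 0.15 for the conservative-only peaks (99.5% of 5434), which had nearly the same median signal (25.04 and 24.96). Peaks shared by both sets at a like signal had a ratio of 0.17 in the optimal set. The optimal-only peaks thus repeated their ranks less well between the libraries than these shared peaks did.

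At promoters, 46.4% of peaks had the motif, against 72.9% in intergenic sequence, a gap of 26.4 points. A consensus limit that is too strict was tested first, with each share corrected for chance matches in the flanks. With 3 mismatches the gap was 19.5 points (bootstrap interval 18.5 to 20.4) against 27.5 with 2, above the limit of 13.8 set for it. The stricter limit of 1 mismatch gave a smaller gap too, of 20.1 points. The fall from 2 to 3 mismatches thus does not show that strictness accounts for part of the gap. With 4 mismatches the gap corrected in this way was 5.62, below that limit, but flanking windows then matched in 60.3% of cases at promoters and 53.0% in intergenic sequence and nearly all summits did (96.1% and 98.1%), so limits looser than 3 mismatches decide nothing and stay open. Weaker signal at promoters was also tested, and the mean gap within signal deciles was 21.9 points (20.9 to 22.8), from 29.6 in the fourth decile to 4.99 in the strongest. Within quintiles of GC content it was 16.5 points (15.0 to 17.8), from 7.83 in the lowest to 27.5 in the highest. For signal and for GC content the limit was 13.2. The highest GC quintile ran from 55.8% to 85.3% and held 7121 of the 13168 promoter peaks, against 1932 intergenic ones. GC content was thus hardly held constant there, and the mean gave each quintile the same weight. The test therefore cannot decide whether GC content accounts for the gap. Up to 3 mismatches, neither the consensus limit nor weaker signal accounted for the gap alone, and GC content stays open. These explanations were not tested together, and no biological explanation was tested, as the design has 1 group.

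Chromosome X had 0.332 times the autosomal density of peaks. If motif supply were the cause, motifs on X should be bound as often as elsewhere, but their bound share was 0.496 times the autosomal one (interval 0.460 to 0.535), while motif density was 0.773 times. Outside repeats, where reads map better, the density ratio was 0.438 (0.413 to 0.464). Both lay below the limit of 0.8, so neither accounts for the deficit alone. A single copy of X in males could weaken its peaks. With a signal limit of 50.9 on autosomes and 25.4 on X the density ratio was 0.495 (0.468 to 0.523), also below 0.8. The scale of the signal is not stated, but among peaks with a perfect motif the median on X was 0.490 times that on autosomes (bootstrap interval 0.451 to 0.612), near the factor of 2 assumed, and among all peaks 1.01 times. With the largest loss in this interval, a factor of 2.22, the density ratio was 0.526 (0.498 to 0.556), and a factor of 4.48 would be needed to reach 0.8. These medians cover only peaks that entered the optimal set. Sites on X that lost too much signal to enter it are missing, so the loss may exceed this interval. A single copy alone fails to account for the deficit only under an assumption that was not tested. It is that weaker peaks and missing sites lose no larger part of their signal than peaks with a perfect motif. Motif supply, repeats and a single copy together gave a ratio of bound shares of 0.813 (0.752 to 0.879). This came from 453 of 1468 motifs on X (30.9%) and 15109 of 39807 on autosomes (38.0%). The combined explanation, which rests on the same assumption, stays open as a hypothesis, and no biological explanation was tested.

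Neighbouring motifs under 5 kb apart pointed the same way in 55.0% of 7191 pairs. Copies of repeats could give such pairs, but with both motifs outside repeats the share was 55.7% (Wilson interval 54.2 to 57.2) of 4236 pairs. The lower limit lay above the 51% set beforehand, so repeats do not account for the excess over random. Local duplication could give such pairs too. Among 6961 pairs under 60% identical around the motif the share was 55.0% (53.8 to 56.1), but this decides nothing, since only 230 pairs were left out and the rest could not have fallen below 53.5%. The 230 similar pairs are themselves too few, as at least 556 would all have to point the same way to give the observed share at its lower limit, and 128 of them did. Duplication that left 60% identity or more thus does not account for the excess, and older duplications that left less stay open. No biological explanation was tested, as the design has 1 group.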
